A study of Rattus norvegicus with 23 samples.

How the data were processed

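The samples were adult female rat hippocampal neural stem cells of wild-type genotype, cells that can give rise to neurons and glia, held on a soft or a stiff substrate in a medium that favours mixed differentiation (DMEM-F12 with N2 supplement, 1 uM retinoic acid and 1% fetal bovine serum). Sample titles give the substrate, a time of 0, 12, 24 or 36 h and a round number. The stiffness of either substrate in units of pressure, and what had been done to the cells by 0 h, are not given in the sources used here. Samples were grouped by substrate and time, which makes 8 groups of 3 libraries each, except soft at 12 h with 2. A soft 12 h library of round 2 was not analysed here. The labels do not say that the rounds are separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

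Per the labels' protocols, total RNA was taken from cell pellets with a column kit that removes genomic DNA, and libraries were made with QuantSeq FWD, which reads tags near the 3' end of polyadenylated transcripts. Gene length therefore has less influence on a count than in whole-transcript libraries, and isoforms that share a 3' end are counted together. The submitters' processing notes name FastQC, HISAT2 2.1.0, HTSeq and the rat build rn6. The annotation release, the strand setting, trimming and any handling of duplicate reads are not given in the sources used here. Genes that overlap or have near-identical copies may share reads. The authors deposited whole-number counts per gene, not normalized, with 1 column per library. Totals ran from 2462360 counts (stiff 12 h replicate 2) to 6811157 (soft 24 h replicate 2). The table lists 32883 Ensembl rat gene identifiers, 18319 of them with at least 1 count, and no line that names no gene.

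The files do not pair the identifiers with gene names, and 0 of 32883 matched the reference table of gene names used here (assembly GRCr8). No name was guessed. The 29 gene lists fixed before the data were examined, the rule for named genes and the gene in the series title could therefore not be used, and neither could checks of GC content, length or cell type. That rule also left identifiers unnamed. As a departure from it, chosen after the data were examined, 4 identifiers are printed: the 2 higher and the 2 lower on stiff at 12 h with the smallest p-values.

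Differences were tested with edgeR 4.0.16 (R 4.3.3), using the quasi-likelihood F test on 1 fit of 8 group means to all 23 libraries, TMM scaling factors, and the filterByExpr filter with its minimum count of 10 and minimum total of 15, which left 11857 genes. A gene is called where the Benjamini-Hochberg adjusted p over those genes is under 0.05. Contrasts were stiff minus soft at each time, their mean with equal weight per time, an F test of 3 coefficients for a stiffness effect that differs from that at 0 h, and 4 time steps averaged over substrates with equal weight. Fold changes are on the log2 scale with the standard error implied by the F statistic. CPM values use the TMM-scaled totals. Principal components were computed on log2 CPM of the tested genes. Contrasts within a substrate, differences of the stiffness effect between pairs of times, and the mean over 0, 24 and 36 h were added after the data were examined. Figures were drawn with matplotlib 3.10.9.

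Replicates were compared before use. Within every group each pair differed by more than sampling noise, with chi-square per degree of freedom from 2.42 to 9.11 over genes with at least 20 counts, so each library was counted as 1 sample. The tests were tried on counts simulated once per comparison, with the real totals and spread and 200 changed genes of known size. Each gene was simulated at its mean over all 23 libraries, not at its level at each time. Of the changed genes, 67 differed by 1.5-fold and 67 by 2-fold. At 2-fold the share recovered was 79.1% for stiff against soft at 0 h, 53.7% at 12 h, 71.6% at 24 h and 68.7% at 36 h. At 1.5-fold it was 50.7%, 25.4%, 47.8% and 41.8%. Calls that were false made up 10.9% of the simulated calls at 0 h and 2.45% to 5.61% in the other 9 comparisons.

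Alternatives set before the data were examined were RLE size factors, no filter on low counts, a filter of at least 5 CPM in 3 libraries, DESeq2 1.42.0, the round number as a block, the compared groups alone, and each library left out in turn. A library was left out only for the comparisons that use its time. Those added afterwards were the 12 h libraries left out, rounds 1 and 3 alone at 12 h, thinning to the smallest total, upper-quartile factors, unscaled totals, and each substrate alone. Other splits of the samples were also counted: all 10 for each single time, and 60 draws for each other comparison, the real one included.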

Results

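The series asked which genes of hippocampal neural stem cells depend on the stiffness of the substrate. Transcript levels were measured in 23 libraries from cells on soft or stiff substrates at 0, 12, 24 and 36 h, with 3 libraries per group and 2 for soft at 12 h. Total counts per library ran from 2462360 to 6811157. At 12 h the ranges did not overlap: the soft libraries held 5428086 and 6519349 counts and the stiff libraries 2462360 to 4803755. In each library 13094 to 14547 genes had at least 1 count, and 11857 genes entered the tests.

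Time separated the libraries more than stiffness did. The first principal component held 54.7% of the variance and ordered the libraries by time, with mean scores of -59.07 on soft and -60.45 on stiff at 0 h, -21.62 and -21.06 at 12 h, 30.28 and 28.10 at 24 h, and 46.99 and 49.64 at 36 h. The second held 11.1% and set the 12 h libraries apart from both earlier and later ones. On this component soft and stiff parted at 12 h, at -36.97 ± 0.127 (SD, n = 2) and -27.44 ± 0.694 (SD, n = 3). Their means also differed at 36 h, in the opposite direction and with overlapping libraries, at 18.69 ± 3.852 on soft and 10.6 ± 4.975 on stiff (SD, n = 3 each).

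**Figure D1:**
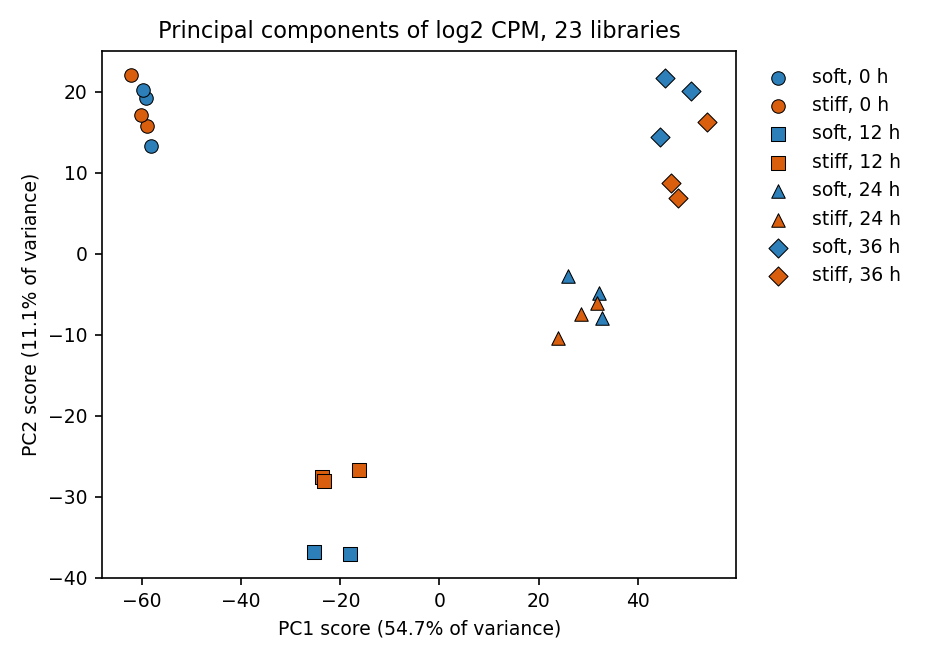
Scores of the 23 libraries on the first 2 principal components of log2 CPM, with colour for substrate and marker shape for time. PC1 (54.7% of variance) follows time, and on PC2 (11.1%) the 2 soft libraries at 12 h lie below the 3 stiff ones.

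At 0 h no gene passed the test between substrates. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment 0 genes were called, 431 had an unadjusted p under 0.05 where 593 would be reached by chance, and DESeq2 also called 0. For this comparison the simulated test recovered 79.1% of 2-fold changes and 50.7% of 1.5-fold changes. Many 2-fold changes would thus have been detected in genes at their mean level over all libraries. Recovery at each gene's own 0 h level was not simulated. With no filter on low counts 12 genes were called.

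At 12 h the substrates differed in 782 genes, 6.6% of those tested. Of these, 635 (81.2%) were higher on stiff and 147 were lower. The differences were mostly moderate, with a median absolute log2 fold change of 0.66, and the larger ones lay almost all in 1 direction: 183 genes were more than 2-fold higher on stiff and 6 more than 2-fold lower, and 40 were more than 4-fold higher. The called genes held 12% of all counts and were more abundant than most, with a median of 62.1 CPM against 26.8 CPM for all tested genes.

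The gene with the smallest p, ENSRNOG00000027006, was 10.3-fold higher on stiff at 12 h (log2 fold change 3.36, SE 0.185, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 2.64e-14). Its level on stiff was 342 ± 26.6 CPM (SD, n = 3) and on soft 33.8 ± 14.7 CPM (SD, n = 2). At 0 h the levels were 299 ± 61.7 and 320 ± 2.86 CPM (SD, n = 3 each), and at 24 h 214 ± 19.1 and 235 ± 36.7 CPM, so it was the soft libraries at 12 h that stood apart from their neighbours in time. ENSRNOG00000024539 followed the same course, with 88.8 ± 2.74 CPM on stiff (SD, n = 3) and 22.6 ± 4.14 CPM on soft (SD, n = 2) at 12 h, against 79.5 CPM on both substrates at 0 h. In the other direction the differences were smaller. ENSRNOG00000022623 was at 302 ± 22 CPM on stiff and 439 ± 39.4 CPM on soft at 12 h (log2 fold change -0.54, SE 0.109). ENSRNOG00000010457 was at 64.9 ± 3.53 CPM on stiff and 93.3 ± 8.38 CPM on soft (log2 fold change -0.52, SE 0.109), and for this gene it was the stiff libraries that lay below their 0 h level of 87.1 ± 4.4 CPM. Its call was lost without soft 12 h replicate 1, at an adjusted p of 0.0611 by the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and over the other alternatives its direction did not change.

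**Figure D2:**
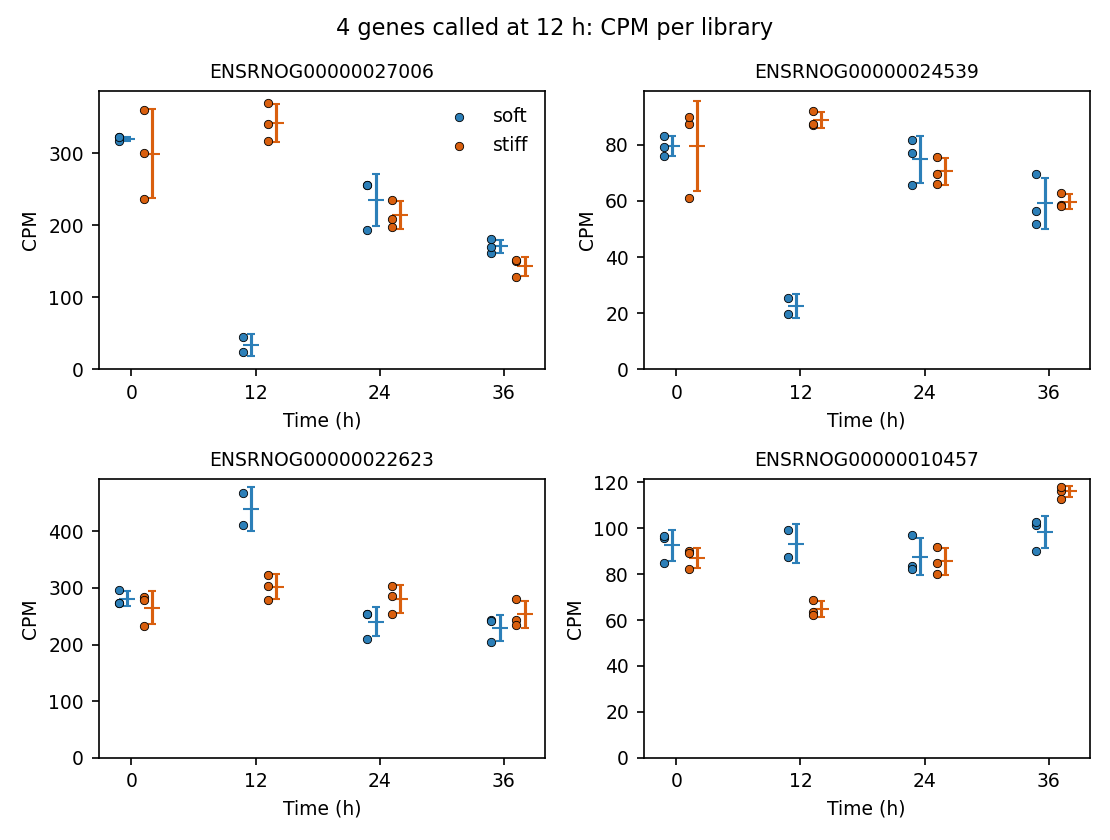
CPM per library (points) with group mean and SD (bars) for the 4 identifiers, by time in hours and substrate, each panel on its own linear axis from 0. At 12 h ENSRNOG00000027006 stood at 33.8 CPM on soft and 342 CPM on stiff, and ENSRNOG00000024539 at 22.6 and 88.8 CPM.

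The count at 12 h rests on 2 soft libraries of greater depth than the 3 stiff ones. It was 336 without soft 12 h replicate 3, where the single soft library left is assumed to vary like the other groups, and 502 without stiff 12 h replicate 2. The 147 lower genes were less stable than the 635 higher ones: 76 and 48 were called lower without soft replicate 1 or 3, and 75, 27 and 91 without stiff replicate 1, 2 or 3. No filter gave 279 lower genes and unscaled totals 80.

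The genes called at 12 h had small median differences at the other times. The 635 genes higher on stiff at 12 h had a median log2 fold change of 0.74 at that time, 0.08 at 0 h, -0.08 at 24 h and -0.09 at 36 h. The 147 lower genes had medians of -0.42 at 12 h, -0.02 at 0 h, 0.05 at 24 h and 0.06 at 36 h. These small medians were not evenly spread around 0: of the 635 genes 74.2% were higher on stiff at 0 h, against 52% of all tested genes, and 21.3% at 24 h and 28.7% at 36 h, against 49.2% and 48.3%. Taken from 0 h to 12 h, the 635 genes had a median change of -0.67 on soft, where 490 were called as fallen, and of 0.01 on stiff, where 58 were called as fallen and 78 as risen. The 147 genes had medians of 0.34 on soft and -0.07 on stiff. These genes were chosen on the same 12 h libraries, which enlarges the medians at 12 h. For genes chosen in rounds 1 and 2 at an unadjusted p under 0.01 and read in round 3, the median change from 0 h among those higher on stiff was -0.67 on soft and -0.03 on stiff, and for genes chosen in round 3 and read in round 1 it was -0.55 and -0.02. Among those lower on stiff the same checks gave 0.18 and 0.17 on soft, below the 0.34 of the called genes.

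**Figure D3:**
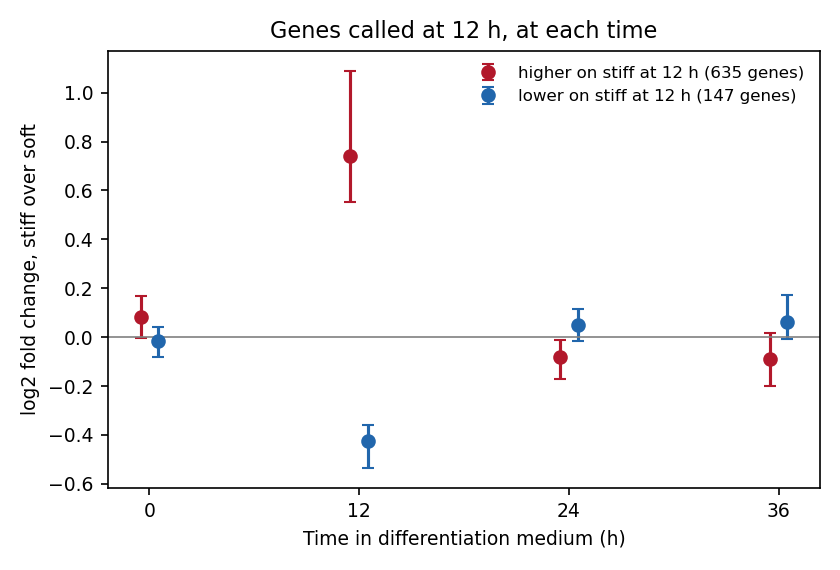
Median log2 fold change of stiff over soft, with bars from the lower to the upper quartile over genes, for the 635 genes higher and the 147 lower on stiff at 12 h, at each time in hours. The medians were 0.74 and -0.42 at 12 h and within 0.1 of 0 at the other 3 times.

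The difference between times was tested directly. The stiffness effect differed from that at 0 h at 1 or more later times in 393 genes (F test of 3 coefficients), or in 674 with no filter on low counts. Of the 393, 361 were among the 782 genes called at 12 h, where 25.9 would be shared by independent lists. Both lists use the 12 h libraries, so part of the excess may come from them. By pairs of times, the effect at 12 h differed from that at 0 h in 222 genes, from that at 24 h in 526 and from that at 36 h in 653. The effect at 24 h differed from that at 0 h in 0 genes by edgeR's test (534 at an unadjusted p under 0.05), and that at 36 h from that at 24 h in 0 (439). Without the 12 h libraries, the F test called 0 genes (483 at an unadjusted p under 0.05), and without soft 12 h replicate 3 it called 160.

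At 24 h no gene passed the test between substrates. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes, with 358 at an unadjusted p under 0.05, and DESeq2 called 0. The simulated test recovered 71.6% of 2-fold changes. With no filter on low counts 8 genes were called.

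At 36 h 8 genes differed, 2 higher and 6 lower on stiff. At 12 h 0 of the 8 were called in either direction, against 6.6% of all tested genes, a share at which 0 of 8 is unremarkable. The 8 genes had a median absolute log2 fold change of 0.77, and 1 was more than 2-fold lower. An unadjusted p under 0.05 was reached by 835 genes, against 593 by chance. The count depended on the method and on single libraries. DESeq2 called 47, a fit of the 36 h libraries alone 28, and no filter gave 97. Leaving out 1 library gave 1 (soft replicate 1 or stiff replicate 3), 3 (stiff replicate 2), 4 (soft replicate 3), 6 (soft replicate 2) or 13 (stiff replicate 1).

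Averaged over the 4 times, 53 genes differed, 51 higher and 2 lower on stiff. These were 12 h differences for the most part: 50 of the 51 were also called at 12 h, which uses some of the same libraries, and the 51 had a median log2 fold change of 1.54 at 12 h and of 0.01 over 0, 24 and 36 h. ENSRNOG00000027006 had an average log2 fold change of 0.72 over the 4 times and of -0.16 without 12 h. Over 0, 24 and 36 h together edgeR's test called 0 genes, with 587 at an unadjusted p under 0.05. The count of 53 became 13 without soft 12 h replicate 3, 33 without stiff 12 h replicate 2, and 119, 28 and 35 without stiff 0 h replicates 1, 2 and 3. It became 94 and 34 without soft 24 h replicates 1 and 3 and 25 without soft 36 h replicate 2. DESeq2 called 101, and no filter on low counts gave 147.

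**Figure D4:**
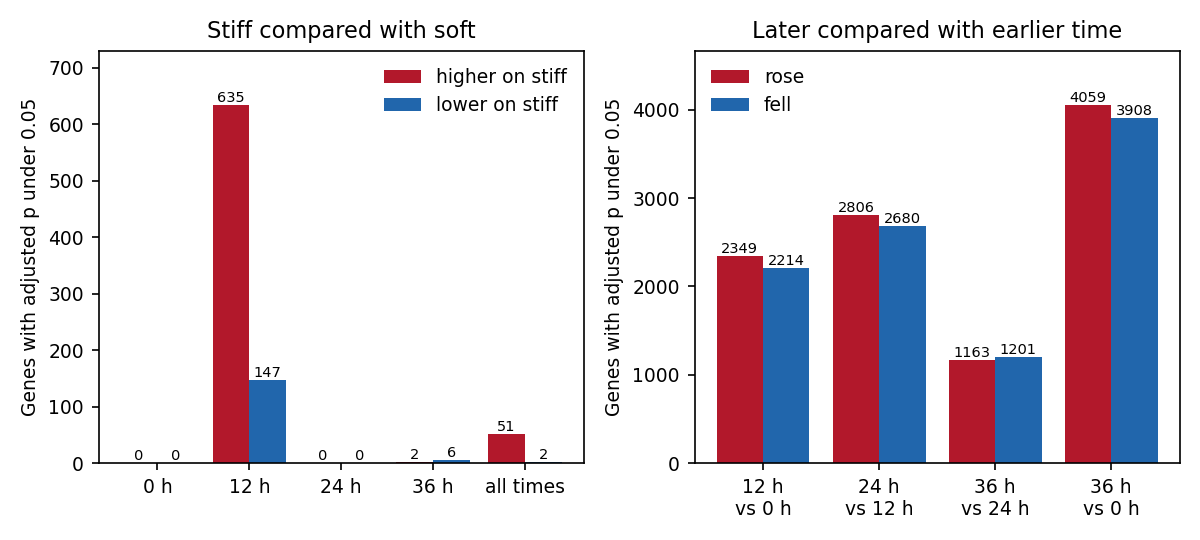
Genes with an adjusted p under 0.05 in edgeR's quasi-likelihood test, by direction, for stiff against soft (left) and for later against earlier times (right), on separate linear axes from 0. Stiffness calls were 635 higher and 147 lower at 12 h and 0 at 0 h and 24 h, and time calls reached 4059 risen and 3908 fallen from 0 h to 36 h.

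Most of the tested genes changed between 0 h and 36 h. From 0 h to 36 h, averaged over substrates, 7967 genes changed (67.2% of those tested), 4059 rising and 3908 falling. More than 2-fold changes were seen in 1541 risen and 1280 fallen genes, and more than 4-fold changes in 530 and 298. The first 12 h brought 2349 risen and 2214 fallen genes, the step from 12 h to 24 h 2806 and 2680, and that from 24 h to 36 h 1163 and 1201. The median absolute log2 fold change of the called genes was 0.50, 0.54 and 0.40 in the 3 steps. For each of these 4 counts, the other scalings, filters and count model, and each library left out in turn, moved the total by less than 1.5 times.

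The course was largely shared by the substrates, which were measured in separate libraries. Across genes, which are not independent replicates, the log2 fold changes from 0 h on soft and on stiff correlated with Pearson's r of 0.664 at 12 h, 0.891 at 24 h and 0.904 at 36 h. Of the genes called on both substrates, 1720 of 1728 moved the same way by 12 h, 4917 of 4917 by 24 h and 5577 of 5579 by 36 h. From 0 h to 12 h 3455 genes were called on soft and 2551 on stiff, and from 0 h to 36 h 6426 and 6819.

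Many genes were called in opposite directions in the first 2 steps. Between 0 h and 24 h, 476 genes rose by 12 h and then fell, and 579 fell and then rose, while 794 rose and 648 fell in both steps. Independent lists would give 530.9, 524, 555.9 and 500.4. The 2 steps share the 12 h libraries, which by itself pulls their fold changes apart. With no effect, simulated steps had a covariance of -0.0284, whereas the observed covariance was 0.0417. The simulation also gave 0 genes in all 4 classes, but no gene changed in it, so few calls could arise. It therefore cannot tell how many of the 476 and 579 reversals come from noise in the shared libraries. Those 2 counts lay near the 530.9 and 524 of independent lists.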

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

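The tests of sampling time, of levels between the sampled times and of a larger 12 h excursion, and the differences between pairs of times, were chosen after the 12 h result was seen. The tests of sampling time and of the excursion were reworded once before they were run, and the split of the excursion test by direction and the simulations for sampling time were added later. For levels between the sampled times, the gene sets and the bound were set when the values were already known, and that test was at first put in place of the one of sampling time, which points the opposite way, so it carries less weight.

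The stiffness effect differed between times. At 12 h it differed from that at 0 h in 222 genes, from that at 24 h in 526 and from that at 36 h in 653, and the F test over all times called 393. At 36 h it differed from that at 0 h in 1 gene, whose log2 difference was -0.90 (SE 0.153, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.0195). For the F test, 1 of 60 splits of the libraries within times, the real one, gave as many calls, and the highest other gave 317. That is a share under 0.05 for the labels of the 4 times jointly, not for those of 12 h. The 9 other splits that kept the 12 h libraries as labelled gave 173 to 317 calls and the remaining 50 gave 8 or fewer, so the F test hangs on the 12 h labels, as the calls over all times do. For stiff against soft at 12 h the real split gave 782 and the highest other 4. Only 10 splits of those 5 libraries exist, too few for a share under 0.05, so chance placement of the 12 h labels is not excluded.

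The calls at 12 h were set against depth, a single soft library and the round with no soft library. With every library thinned to the smallest total, 558 of the 782 genes were still called, so most calls do not need the unequal totals. Thinning keeps each library's gene proportions, so it cannot test a difference in composition that goes with depth. Without the stiff library of round 2, 472 of the 782 were still called, more than that round as the whole cause would leave. This rests on the genes higher on stiff: only 27 genes were called lower in that fit, against 147, so for those the round is not argued against. Genes chosen in rounds 1 and 2 had the same sign in round 3 in 94.1% of cases, and those chosen in round 3 the same sign in rounds 1 and 2 in 94.9%, which argues against a single soft library. By direction these shares were 96.2% and 97.3% for genes higher on stiff, and 86.8% and 77.4% for genes lower on stiff, whose median log2 fold change went from -0.91 in round 3 to -0.22 in rounds 1 and 2. An effect of the substrate at 12 h stays open, as does anything else that both soft 12 h libraries share.

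The soft level at 12 h was low in most of these genes. A candidate explanation is that the soft libraries were in effect at another point of the time course. In part, 1 test goes with it. Across the 782 genes the soft minus stiff difference followed the step from stiff 12 h toward 24 h with coefficients of 0.744 to 0.878. In 20 simulations with no relation to that step they were 0.349 to 0.674, so coefficients above 0, the predicted outcome, arose there too. With genes chosen in separate libraries they were 0.938 and 0.623 (r squared across genes 0.26 and 0.21) against at most 0.417 and 0.406. Toward 0 h the coefficients over the 782 genes, 0.185 to 0.362, largely lay within the 0.0567 to 0.344 of the simulations. With separate libraries 0.345 and 0.242 lay above the highest simulated 0.133 and 0.156, so both neighbouring times exceeded the simulations there. The simulated gene sets differed in size from the real ones. Medians were 562 against 782, and in separate libraries 543.5 against 364 and 531.5 against 512. How far this mismatch accounts for the excess was not tested. The stiff steps are too small to make up the difference in full, with medians of -0.216 and -0.212 toward 24 h against -0.833 and -0.611 for soft minus stiff in the genes higher on stiff, and the first principal component put both substrates at about the same point at 12 h (-21.62 and -21.06). Against a level merely between those of the sampled times, the soft 12 h level lay beyond that of all 7 other groups in 65.4% of genes chosen in the other round pair (74.5% and 66.4% of those higher on stiff, 43.7% and 37.1% of those lower), compared with 17.2% to 19.2% of all tested genes. A larger form of a change also made on stiff is argued against for the genes higher on stiff, of which 47.4% had the same sign of excursion on both substrates (63.5% and 68.5% of all tested genes in the 2 checks), but is left undecided for those lower on stiff, at 70.4% (51.6% over both). A faster or transient course on soft, a different sampling moment and an effect of stiffness at this time may each account for part of the pattern, and no biological explanation was singled out.

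The calls over all 4 times depend on the same libraries. In 10 of 60 splits, the real one included, at least as many genes were called as the real 53, with 462 as the highest other, so chance placement cannot be excluded for this average. The 9 other splits with as many calls were the 9 that kept the 12 h libraries as labelled, a structure of the samples that comes from 12 h.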

How the results depend on the processing

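The alternatives named as added in the account of the processing were chosen after the data were examined; the others were fixed before. The cause of each change below was not tested, except where fewer libraries are the change itself. With no filter on low counts more genes were tested, but that was not the only change. For ENSRNOG00000027006 at 12 h the log2 fold change was 3.341 without the filter and 3.358 with it. Its adjusted p (edgeR quasi-likelihood test, Benjamini-Hochberg) was 1.84e-140 and 2.64e-14, so the estimated spread differed as well. With no filter on low counts, the stiffness calls became 12 at 0 h, 8 at 24 h, 97 at 36 h, 147 over all times and 674 for the F test. DESeq2 gave 47 at 36 h and 101 over all times, and the 36 h groups alone gave 28. With 0, 24 and 36 h only, the average over times called 0, and the log2 fold changes of ENSRNOG00000027006 and ENSRNOG00000024539 turned to -0.1623 and -0.02038. With no 12 h libraries the F test called 0. With rounds 1 and 3 only at 12 h, 502 were called there. The other 52 totals lay within 1.5 times of the main count, and at 12 h unscaled totals put 90.3% of calls higher on stiff, against 81.2%.

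Leaving out each library in turn gave 0 calls throughout at 0 h and at 24 h, 336 to 672 at 12 h, 1 to 13 at 36 h, 13 to 119 over all times, 160 to 433 for the F test, 3785 to 4520 for 12 h against 0 h, 4758 to 5341 for 24 h against 12 h, 1897 to 2282 for 36 h against 24 h and 7686 to 7822 for 36 h against 0 h. Over all times the libraries that moved the count by more than 1.5 times were soft 24 h replicate 1 (94 without it), stiff 0 h replicates 1 (119), 2 (28) and 3 (35), soft 36 h replicate 2 (25), stiff 12 h replicate 2 (33), soft 12 h replicate 3 (13) and soft 24 h replicate 3 (34).

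Samples share only a round number. Deviations from the group means correlated between same-numbered libraries from -0.087 to 0.148, and 21 of 23 libraries were closest to their own number, a hint from the data and not the design. With the replicate block 48 genes were called at 36 h and 94 over all times, and no other total moved by 1.5 times (969 at 12 h, 569 for the F test), though at 12 h the genes lower on stiff went from 147 to 258 and the share higher from 81.2% to 73.4%.

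The tests of the gene lists and their alternatives were not run, because identifiers were not matched to names. Small changes are detected in part only: at 12 h the simulated test recovered 25.4% of 1.5-fold and 53.7% of 2-fold changes. Depth was not separated from the small number of libraries in this.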

Other observations

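That splits would be counted was set before the data were examined. Afterwards the number drawn was lowered to 60 to keep the computation short. This held for the time steps, the average over all times and the F test.

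For the time steps, the real split of 60 gave the most calls in each. It gave 4563 from 0 h to 12 h (highest other 3320) and 5486 from 12 h to 24 h (3235). From 24 h to 36 h it gave 2364 (760), and from 0 h to 36 h 7967 (5668). In each step 1 of 60 splits, the real one, was as large. That share is under 0.05 and argues against chance placement of the time labels without excluding it. For stiff against soft at single times there are 10 splits, too few for a share under 0.05: at 0 h 10 of 10 gave at least the real 0 calls (highest other 1), at 24 h 10 of 10 gave the real 0 (highest other 0), and at 36 h 1 of 10 gave the real 8 (highest other 1).

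The 100 most abundant genes of each library took a mean of 24.7% of counts in the soft 12 h group and 23.03% in the stiff 12 h group.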
